A study of Pseudomonas putida with 18 samples.

How the data were processed

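The data are 18 RNA-seq libraries of *Pseudomonas putida* NCTC 10936 in 6 groups of 3 flasks: controls at 0, 6 and 24 h, nZVI at 6 and 24 h, and dissolved iron at 24 h. Per the labels, cells were grown to mid-log phase, pelleted and moved to reservoir water, rRNA was depleted, libraries were made with the NEBNext Ultra II RNA kit and sequenced as single reads of 85 bases. The labels do not say that the kit kept the strand, so reads from the opposite strand of a gene cannot be told apart from its own. Per the submitters' processing notes, reads were aligned with STAR, counted with HTSeq and tested with DESeq2. Their versions, the strand setting, the genome build and the annotation are not given in the sources used here. Gene identifiers are in the style of strain KT2440, with 3653 locus tags and 2067 symbols. The labels also mention 3 h samples that the series does not hold.

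The authors deposited a sample table of log2 values for 5720 genes, which are variance-stabilised normalised counts centred on each gene's mean. The authors also deposited 3 tables of genes under an adjusted p of 0.05, one per exposure. Their mean of normalised counts over all libraries is a signal computed by the authors with size factors. Their log2 fold change and its standard error come from the authors' DESeq2 run, with positive values where the control was higher. The Wald score of each gene is, as deposited, that fold change over its standard error. The raw and adjusted p-value columns are the authors' own, made before the files were deposited, and no gene above the threshold is listed. In the 24 h nZVI table the fold column is headed 6 hours although its values are those of 24 h.

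The centred values were turned back into normalised counts and whole reads. The closed form of the variance-stabilising function has 2 parameters, fitted on 7 genes as 0.01571 and 1.844. The level of each gene was set from the authors' mean for 4141 genes, from zeros shared by several libraries for 130, and from a search for the level that makes all 18 values whole for 1449. With a tolerance of 0.01 reads 100.0% of values were whole, and no gene had more than 1 solution. The inversion was tested on simulated data, where 5720 of 5720 genes were recovered. Libraries held 1434437 to 4204283 reads on genes, and 1 read was worth 0.698 to 1.64 normalised counts. Single reads are not independent molecules, so this covers counting error only.

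Tests were run in R 4.3.3 with limma 3.58.1 on the deposited values with each gene's mean restored. The fit had 1 mean per group, a spread shared by all 6 groups, an intensity trend and no robust option, and p-values were two-sided and adjusted by Benjamini and Hochberg over 5720 genes, with a threshold of 0.05. The 7 comparisons were each exposure with its control of the same hour, nZVI with dissolved iron at 24 h, the change of the nZVI effect from 6 h to 24 h, and the controls at 6 h and 24 h with those at 0 h. Groups, comparisons and the rule for naming genes were written before the data were examined. No filter was applied. Folds are ratios of mean normalised counts. On simulated data with 200 changed genes and a dispersion of 0.01, 96 to 98% of changes of 2-fold, 64 to 66% of changes of 1.5-fold and 12 to 16% of changes of 1.25-fold were recovered, and 2.1 to 8.6% of calls were false. All simulated genes had the same dispersion, and no simulated library stood apart. Changes were set only in genes with a mean of at least 10 normalised counts.

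Gene lists written before the data were examined were matched by symbol: oxidative stress defence, pyoverdine and iron uptake, iron storage and Fur regulation, iron-sulfur cluster assembly, heat shock and protein quality control, SOS response and DNA repair, flagella and chemotaxis, ribosomal proteins, TCA cycle and glyoxylate shunt, respiratory chain and ATP synthase, metal efflux and resistance, RND multidrug efflux pumps, fatty acid and membrane lipid synthesis, outer membrane porins and cell wall, exopolysaccharide and adhesion, general stress and stationary phase, polyhydroxyalkanoate metabolism, type VI secretion, nitrogen assimilation, phosphate and sulfur starvation, prophage, pyocin and mobile elements, and stable RNA. Afterwards, on names alone, the rsm rRNA methyltransferases were removed from general stress, ompR from porins and lpdV from the TCA cycle, and rRNA locus tags were added to stable RNA. The metal list also holds metal uptake genes such as nikA and znuC. The RND list also holds efflux genes of other families, such as emrA, emrB and norM, and the regulator gene mexT. Lists with at least 5 members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. The genes tufA and tufB and the rRNA copies are near identical, so their reads cannot be assigned with certainty.

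Named genes are those with a symbol among the 8 largest rises and 8 largest falls of each exposure that passed and had all 3 exposed flasks beyond the 3 controls, up to 4 members of each list with the smallest p, and a set of stress, iron and motility genes written down beforehand. For the other comparisons 5 rises and 5 falls were taken. The tmRNA, the values of ynfM and rpiA with dissolved iron and the values per library of replicate 2 of the 6 h controls were chosen after the values were seen.

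Alternatives were other pseudocounts, a filter at a mean of 10 normalised counts, libraries rescaled to the same median, quantile normalisation, no trend, only the groups compared in the fit, the replicate number as a block, an added minimum absolute log2 difference of 1, and each library left out in turn. Added after seeing the data were voom on the recovered reads, log2 of the normalised count plus 1, library quality weights, leaving out replicate 2 of the 6 h controls everywhere, and that together with only the groups compared. TMM against DESeq2 size factors was planned for deposited raw counts and was not run. Simulations of shared controls numbered 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Gene lengths came from the annotation of *P. putida* NBRC 14164 matched by symbol, since no genome of the studied strain was at hand.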

Results

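RNA sequencing measured transcript levels of 5720 genes in 18 libraries of the soil and water bacterium *Pseudomonas putida* NCTC 10936 held in reservoir water. Nanoscale zero-valent iron (nZVI), metallic iron particles that corrode in water and release dissolved iron, was given at 100 mg/L and sampled after 6 h and 24 h. Dissolved iron alone was given at 44.5 µg/L and sampled after 24 h. Unexposed controls were sampled at 0 h, 6 h and 24 h, and each of the 6 groups had 3 flasks. Per the labels, a magnet took the particles out of nZVI samples before RNA extraction, and no such step is stated for the other samples. Reads on genes numbered 3334619 to 3828773 per library in the 0 h controls, 1589029 to 2287065 in the 6 h controls and 3570060 to 4204283 in the 24 h controls. They numbered 2628143 to 2835150 after 6 h of nZVI, 2691897 to 2896121 after 24 h of nZVI and 1434437 to 1941247 after dissolved iron. Single reads corresponded to 0.698 to 1.64 normalised counts. The strand setting of the counting is not given, so reads from the opposite strand of a gene cannot be told apart from its own. Levels are given as normalised read counts, mean ± SD over n = 3 flasks, and folds are ratios of these means. For an exposure, rose and fell mean higher and lower than in the controls of the same hour, not a change over time. Log2 differences and tests are on the deposited variance-stabilised scale, where a difference is smaller than the log2 of the fold for genes with few reads. They average log values, so 1 low library in a group can also make a difference larger than the log2 of the fold.

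The dissolved iron libraries stood furthest from the others, and the 0 h controls lay at the opposite end of the first principal component, which carried 69.1% of the variance. Dissolved iron libraries lay at 38.6 to 38.9 on it, 6 h controls at 4.6 to 22.5, 6 h nZVI at -3.4 to -2.9, 24 h nZVI at -7.8 to -6.4, 24 h controls at -16.2 to -13 and 0 h controls at -24.4 to -24.2. Replicate 2 of the 6 h controls stood apart from its siblings. It held 621.2 normalised counts of the flagellar gene flgF against 4219.3 and 4106.1, and 3328.3 of the succinate dehydrogenase gene sdhA against 9478.9 and 9342.4.

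**Figure D1:**
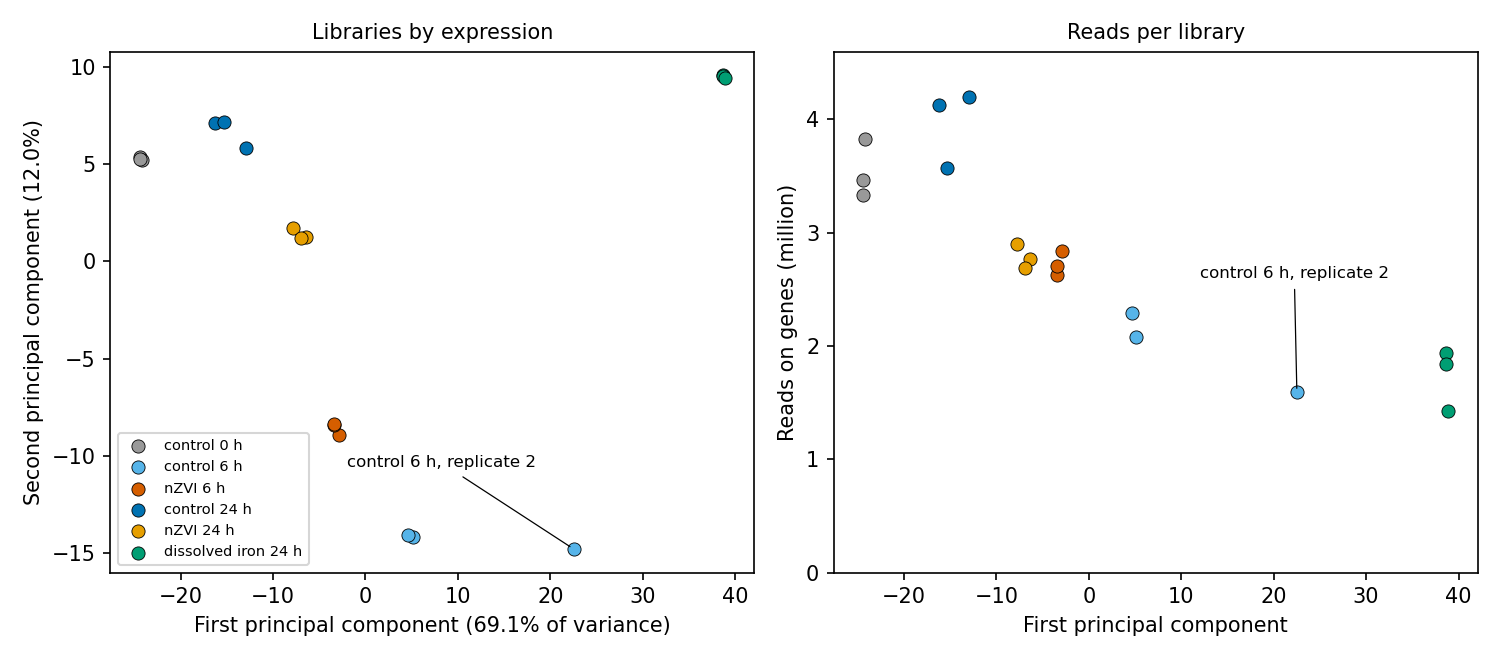
Each of the 18 libraries, coloured by its group, on the first and second principal components of the deposited log2 values (left) and its total reads on genes with its first component (right). The dissolved iron libraries lie at 38.6 to 38.9 on the first component, and replicate 2 of the 6 h controls, with 1589029 reads, lies at 22.5.

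The 6 h nZVI comparison asks how cells differed from the 6 h controls after a short exposure. Among genes with a symbol, the largest rises were in ynfM, a predicted membrane transporter of the major facilitator family, and rpiA, which interconverts pentose phosphates. ynfM rose from 1055.6 ± 121.4 to 3632.1 ± 30.1 normalised counts, 3.44-fold (log2 difference 1.71, SE 0.07, adjusted p 3.2e-11). rpiA rose from 784.7 ± 23.4 to 2149.5 ± 30.4, 2.74-fold (log2 difference 1.36, SE 0.05, adjusted p 3e-12). Among the falls, tufB, elongation factor Tu, was 1.78-fold lower, rplM, ribosomal protein L13, 1.92-fold and miaA, a tRNA modification enzyme, 1.69-fold. The lipoprotein transport gene lolC, the polyamine gene spuA and the coenzyme A synthesis gene dfp fell 1.69-fold, 1.88-fold and 1.59-fold. With nZVI lolC had 2595 normalised counts, still above its level in the 0 h controls given below.

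Ribosomal protein genes were together lower than in the 6 h controls: 20 of 54 fell, none rose and 34 did not pass the test (camera adjusted p 1.1e-05, and adjusted p 0.049 with an estimated correlation). Against other genes their median reads per kilobase lay at -1.84 log2 in the 0 h controls, -1.14 with nZVI and -0.86 in the 6 h controls. With nZVI they were thus higher than at 0 h, by less than in the 6 h controls. The number that fell was 22 adjusted over the list alone. Examples were rplM, rpsG (1.75-fold lower), rplR (1.8-fold lower) and rplB (1.57-fold lower). Without replicate 2 of the 6 h controls 19 fell, camera gave adjusted p 0.00013, and adjusted p was 0.15 with an estimated correlation. These genes carried few reads, with a median of 37 normalised counts against 181.9 for all genes. In the exopolysaccharide and adhesion list 8 of 28 genes fell and 3 rose (adjusted p 0.061, and adjusted p 0.094 with an estimated correlation), with algC 1.54-fold and peaE 1.4-fold lower; the set passed without replicate 3 of the 6 h controls (adjusted p 0.04), without replicate 2 of the 6 h nZVI group (adjusted p 0.044) and after quantile normalisation (adjusted p 0.0075). It did not without replicate 1 or 2 of the 6 h controls (adjusted p 0.13 and 0.094) or replicate 1 or 3 of the 6 h nZVI group (adjusted p 0.062 and 0.099). In the SOS response and DNA repair list 6 rose and 6 fell of 38, with recX, a RecA regulator, 1.63-fold lower and ruvA, a branch migration gene, 1.47-fold higher.

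Oxidative stress genes did not move as a set at 6 h: of 30, 5 rose, 3 fell and 22 did not pass. The thioredoxin gene trxC rose 1.4-fold and the iron superoxide dismutase gene sodB fell 1.28-fold. The catalase genes katA (0.919-fold, adjusted p 0.391) and katG (1.02-fold, adjusted p 0.882), the peroxidase gene ahpC (0.974-fold, adjusted p 0.727) and the peroxide sensor oxyR (1.18-fold, adjusted p 0.0586) did not pass; oxyR had adjusted p 0.0273 and 0.00849 without replicate 1 or 3 of the 6 h controls. Of 24 pyoverdine and iron uptake genes 4 rose and 3 fell, among them the pyoverdine synthesis genes pvdH (1.4-fold lower) and pvdD (1.21-fold lower). In iron storage and Fur regulation 1 of 6 rose and 1 fell, and the iron regulator gene fur was 1.51-fold higher, with a log2 difference of 0.49 that was 0.28 without replicate 2 of the 6 h controls. In iron-sulfur cluster assembly 3 rose and 5 fell of 14, with the cysteine desulfurase gene iscS-I 1.49-fold lower. The DNA repair gene recA (0.898-fold, adjusted p 0.25) and the general stress regulator gene rpoS (0.98-fold, adjusted p 0.933) did not pass.

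The flagellar rod, ring and hook genes flgF to flgK were 1.76 to 1.85-fold higher after 6 h of nZVI, but this size rested on replicate 2 of the 6 h controls. For flgF the log2 difference was 1.26 (SE 0.41, adjusted p 0.0289) and fell to 0.4 (SE 0.04, adjusted p 2.69e-11) without that library. The call of flgF was also lost without replicate 1, 2 or 3 of the 6 h nZVI group (adjusted p 0.0681, 0.0698 and 0.0725), as were those of flgG to flgK (adjusted p 0.0636 to 0.0829). Of 43 genes for flagella and chemotaxis 16 rose and 8 fell, among the latter flhF, which places the flagellum at the cell pole, 1.65-fold lower. The median of that list was -0.07, its mean 0.22, and the set test did not pass (adjusted p 0.78). In this list 16 rose and 13 fell adjusted over the list alone. yajD was 2.03-fold lower, with a log2 difference of -0.69 that was -0.27 without replicate 2 of the 6 h controls, and its call was lost without replicate 1 or 3 of the 6 h nZVI group (adjusted p 0.0563 and 0.0641).

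In central metabolism 9 of 28 TCA cycle and glyoxylate genes rose and 3 fell at 6 h, with the fumarase gene fumC-II 1.49-fold higher and the malate dehydrogenase gene mdh 1.45-fold lower. Of 45 respiratory genes 10 rose and 8 fell, among them ndh 1.31-fold higher and the ATP synthase gene atpC 1.57-fold lower. Of 17 RND multidrug efflux genes 8 rose and 4 fell, with mdtC 1.36-fold higher, and of 39 metal resistance genes 4 rose and 7 fell, with czcB-I 1.31-fold lower. Of 54 genes for outer membrane porins and cell wall 5 rose and 11 fell, with tolB 1.39-fold and bamE 1.31-fold lower. In heat shock and protein quality control 9 rose and 5 fell of 27, in nitrogen assimilation 8 and 1 of 28, in phosphate and sulfur starvation 9 and 4 of 44, in general stress and stationary phase 6 and 3 of 19, and in fatty acid and membrane lipid synthesis 5 and 2 of 23. Of 3 polyhydroxyalkanoate genes 1 rose, of 7 prophage genes 1 fell, and no gene passed among 4 for type VI secretion and 21 for stable RNA. Adjusted over the list alone, the counts that changed were 10 and 7 for heat shock, 9 and 4 for the TCA cycle, 9 and 5 for RND efflux, 4 and 11 for the outer membrane, 2 and 1 for iron storage, 2 and 0 for polyhydroxyalkanoate and 0 and 0 for prophage. Without replicate 2 of the 6 h controls, 12 rose and 6 fell in the TCA cycle, 2 and 8 in metal resistance, 7 and 3 in heat shock, 4 and 4 in SOS and DNA repair, 3 and 5 in pyoverdine, 8 and 0 in nitrogen assimilation and 0 and 0 in prophage genes. By fry, iron-sulfur cluster assembly (adjusted p 0.0044), metal resistance (0.0029), outer membrane (0.00021), exopolysaccharide (9.5e-06) and ribosomal proteins (9.5e-06) passed as lower at 6 h. Nitrogen assimilation (0.0011) and phosphate and sulfur (0.019) passed as higher, and no other list passed.

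In all, 1778 genes passed an adjusted p of 0.05 at 6 h, 999 higher and 779 lower with nZVI. The count was 1107, 1002 and 975 without replicates 1, 2 and 3 of the 6 h nZVI group, and 45 (12 higher, 33 lower) when only these 6 libraries entered the fit, where replicate 2 of the controls widened the spread. With only these groups and without that library it was 1469.

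The 24 h nZVI comparison asks what remained or appeared after a day. Among genes with a symbol ynfM and rpiA again had the largest log2 differences of those that rose: ynfM went from 710.7 ± 44.0 to 3225.5 ± 257.5 normalised counts, 4.54-fold (log2 difference 2.05, SE 0.07, adjusted p 1.32e-12), and rpiA from 664.4 ± 4.38 to 1878.2 ± 33.0, 2.83-fold (log2 difference 1.39, SE 0.05, adjusted p 1.32e-12). The protocatechuate degradation gene pcaC rose 2.28-fold, the phosphomannomutase gene cpsG 2.52-fold, the DNA methylase gene hsdM 2.39-fold and ihfA, a subunit of the DNA-bending integration host factor, 2.15-fold. The glyoxalase gene gloB rose 1.74-fold. pqqD-II, a gene of pyrroloquinoline quinone synthesis with few reads, rose from 4.33 ± 2.66 to 53.0 ± 12.1, 12.3-fold.

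Falls at 24 h were smaller. The leucine synthesis gene leuB fell 1.65-fold, the tyrosine degradation gene hpd 1.58-fold, the cyclopropane fatty acid synthase gene cfa 1.57-fold and the efflux gene mdtC 1.51-fold. rnhA fell 1.68-fold and prmB 1.52-fold with all libraries, but rnhA had adjusted p 0.0557 to 0.113 without any 1 of the 6 libraries of this comparison. prmB had adjusted p 0.0564 to 0.0972 without replicate 1 or 2 of the 24 h controls or without replicate 1, 2 or 3 of the 24 h nZVI group.

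Respiratory genes leaned down after 24 h of nZVI: 10 of 45 genes of the respiratory chain and ATP synthase fell and 1 rose (adjusted p 0.026, and adjusted p 0.18 with an estimated correlation). Among them were the NADH dehydrogenase gene nuoF (1.32-fold lower), the cytochrome bc1 gene petB (1.46-fold lower) and the cyanide-insensitive oxidase gene cioB (1.37-fold lower). These counts were 11 and 1 adjusted over the list alone. This set call was lost without replicate 2 of the 6 h controls (15 fell, 1 rose, adjusted p 0.17), replicate 1 of the 24 h controls (adjusted p 0.063) or replicate 2 of the 24 h nZVI group (adjusted p 0.056). The isocitrate dehydrogenase gene icd was 1.43-fold lower; in its list, the TCA cycle and glyoxylate shunt, 1 rose and 2 fell of 28, and without replicate 2 of the 6 h controls 2 rose and 13 fell (adjusted p 0.021, and adjusted p 0.13 with an estimated correlation). Of 17 RND efflux genes 4 fell and 1 rose, and without that library 10 fell and 2 rose (adjusted p 0.021, and adjusted p 0.22 with an estimated correlation).

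Metal resistance genes that passed all rose: 7 of 39, including the copper sensor gene copS (2.18-fold), the copper and silver efflux gene cusA (1.41-fold) and the arsenite pump gene arsB-II (1.6-fold). The set test gave adjusted p 0.19, and without replicate 2 of the 6 h controls 9 rose and 4 fell. Of 54 ribosomal protein genes 4 rose, among them rplA (1.64-fold), and none fell (adjusted p 0.026, and adjusted p 0.18 with an estimated correlation). With replicate 2 of the 6 h controls left out 10 rose and 2 fell, and the set call was lost without replicate 1 or 2 of the 24 h controls (adjusted p 0.11 and 0.054) and after quantile normalisation (adjusted p 0.85). Stable RNA, kept as a check on the libraries because rRNA had been depleted, was higher: 14 of 21 rRNA genes rose (adjusted p 1e-11, and adjusted p 0.18 with an estimated correlation). rRNA took 0.056 to 0.142% of reads against 0.027 to 0.034% in the 24 h controls. The 23S gene PP_23SD, whose reads cannot be told from those of the other copies, had 276.2 ± 115.9 normalised counts against 65.8 ± 7.62.

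Few stress and iron genes passed at 24 h. sodB rose 1.31-fold and the ferredoxin reductase gene fpr-I fell 1.54-fold, and of 30 oxidative stress genes 1 rose and 3 fell (5 and 9 without replicate 2 of the 6 h controls). katA (1.2-fold, adjusted p 0.08), katG (0.899-fold, adjusted p 0.26), ahpC (0.939-fold, adjusted p 0.429) and recA (0.968-fold, adjusted p 0.809) did not pass. fur (0.797-fold, adjusted p 0.125) did not pass either, but had adjusted p 0.000314 without replicate 2 of the 6 h controls, and katA had adjusted p 0.00171 without it. Of 24 pyoverdine and iron uptake genes 4 rose and 1 fell (6 and 6 without that library), with pvdE 1.32-fold and pvdI 1.44-fold higher and pvdY 1.36-fold lower. In the exopolysaccharide and adhesion list 5 of 28 rose and 1 fell (9 and 4 without that library; adjusted p 0.099, adjusted p 0.18 with an estimated correlation and adjusted p 0.012 after quantile normalisation), with algP 1.94-fold and algL 1.59-fold higher.

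Most counts in the other lists at 24 h rested on replicate 2 of the 6 h controls, which enters only through the shared spread, and counts per list were not computed with another library left out. Of 54 outer membrane and cell wall genes 7 rose and 3 fell (11 and 8 without that library), with mreB 1.64-fold and mrcA 1.37-fold higher. Of 43 flagella and chemotaxis genes 3 rose, among them the export gene flhB 1.65-fold, and none fell; the median was 0.05 and the mean -0.04, and without replicate 2 of the 6 h controls 7 rose and 16 fell (adjusted p 0.26). In SOS and DNA repair 2 rose and 3 fell of 38 (8 and 10 without that library), and in heat shock 3 rose and none fell of 27 (4 and 11 without it). In nitrogen assimilation 4 rose and 3 fell of 28 (5 and 9 without it), in phosphate and sulfur starvation 4 and 5 of 44 (7 and 13), in fatty acid synthesis 1 and 2 of 23 (2 and 6), in iron storage 2 and 0 of 6 (2 and 1), in iron-sulfur cluster assembly 1 and 0 of 14 (2 and 1), in general stress 0 and 1 of 19 (4 and 6) and in prophage genes 1 and 0 of 7. No polyhydroxyalkanoate or type VI secretion gene passed, and without replicate 2 of the 6 h controls all 3 polyhydroxyalkanoate genes fell. Adjusted over the list alone, the counts that changed were 2 and 3 for oxidative stress, 4 and 2 for pyoverdine, 0 and 1 for the TCA cycle, 1 and 5 for RND efflux, 2 and 2 for fatty acids, 6 and 1 for exopolysaccharide, 0 and 0 for general stress and 5 and 5 for phosphate and sulfur. By fry, iron-sulfur assembly (adjusted p 0.016), ribosomal proteins (0.006), metal resistance (0.0025), exopolysaccharide (0.0015) and stable RNA (0.0017) passed as higher. The TCA cycle (0.029), respiratory genes (0.00021) and RND efflux (0.032) passed as lower, and no other list passed.

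In all, 830 genes passed at 24 h, 398 higher and 432 lower with nZVI, and 18 of them had an absolute log2 difference of at least 1, all higher. The count was 344 and 408 without replicates 1 and 2 of the 24 h controls, 445, 544 and 496 without replicates 1, 2 and 3 of the 24 h nZVI group, and 2074 without replicate 2 of the 6 h controls, which enters here only through the shared spread. It was 479 after quantile normalisation, 1899 when only the groups compared entered the fit and 2248 with library quality weights. The balance of directions moved too. Higher and lower were 283 and 196 after quantile normalisation, 208 and 136 without replicate 1 of the 24 h controls, 367 and 520 with libraries rescaled to the same median, 769 and 1305 without replicate 2 of the 6 h controls, 679 and 1220 with only the groups compared and 869 and 1379 with quality weights.

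The dissolved iron comparison asks what iron in solution does without particles. Transcripts of some flagellar genes and of succinate dehydrogenase genes were far lower. flgF fell from 7565.4 ± 259.9 to 93.8 ± 3.83 normalised counts, 80.6-fold (log2 difference -5.47, SE 0.41, adjusted p 1.72e-09), and flgH, flgG, flgI, flgJ and flgK fell 75.9, 74.4, 35.2, 23.4 and 19.6-fold. The flagellin gene fliC fell 7.56-fold. sdhA fell from 14477.2 ± 167.9 to 562.0 ± 22.1, 25.8-fold (log2 difference -4.49, SE 0.25, adjusted p 4.65e-11), and sdhB fell 19.2-fold.

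Among the rises with dissolved iron, hmgR, regulator of homogentisate breakdown, rose from 309.3 ± 43.8 to 2312.9 ± 72.3, 7.48-fold (log2 difference 2.61, SE 0.07, adjusted p 7.36e-15), and the protocatechuate genes pcaC and pcaD rose 7.3-fold and 4.73-fold. The argininosuccinate lyase gene argH rose 3.66-fold and the propionyl-CoA synthetase gene prpE 3.37-fold. recA, which starts the SOS response, rose from 127.8 ± 12.7 to 544.3 ± 30.3, 4.26-fold (log2 difference 1.6, SE 0.07, adjusted p 2.79e-12), and the SOS repressor gene lexA-I, the division inhibitor gene sulA and recX rose 3.8, 3.68 and 4.32-fold. Of 38 SOS and DNA repair genes 20 rose and 12 fell, and camera did not pass (adjusted p 0.19, adjusted p 0.2 with an estimated correlation and adjusted p 0.047 after quantile normalisation). The fry test passed as higher (adjusted p 3.1e-10). The oxidised guanine repair gene mutM was among those that fell, 3.48-fold.

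Ribosomal protein genes rose together: 43 of 54 rose and 1 fell (adjusted p 8e-07, and adjusted p 0.025 with an estimated correlation). Adjusted over the list alone, 44 rose and 1 fell. rplA rose 4.49-fold, rplM 4.01-fold, rplY 3.25-fold and rpsD 2.54-fold, from levels under 100 normalised counts in the 24 h controls. Without replicate 2 of the 6 h controls 44 rose, with adjusted p 2.4e-05, and adjusted p 0.061 with an estimated correlation. rRNA rose beside them: 15 of 21 stable RNA genes rose (adjusted p 0.014, and adjusted p 0.64 with an estimated correlation), and rRNA took 0.087 to 0.132% of reads. Phosphate and sulfur starvation genes leaned down, with 29 of 44 lower and 9 higher (adjusted p 0.016, and adjusted p 0.11 with an estimated correlation), among them the sulfonate transport genes ssuC (3.66-fold lower) and tauC (2.46-fold lower) and the alkylsulfatase gene atsK (2.35-fold lower).

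Oxidative stress genes went both ways with dissolved iron: of 30, 8 rose and 14 fell (adjusted p 0.58). The iron superoxide dismutase gene sodB rose 2.2-fold while the manganese enzyme gene sodA fell 2.62-fold. The glutathione synthesis gene gshA rose 1.61-fold and katA 1.3-fold, whereas katG fell 1.58-fold and the thioredoxin gene trx 2.79-fold. ahpC (1.07-fold, adjusted p 0.243) and oxyR (0.944-fold, adjusted p 0.469) did not pass. In iron storage and Fur regulation 4 of 6 fell and 1 rose: fur fell 2.29-fold and the bacterioferritin gene bfr-I 1.8-fold, and iscR, the iron-sulfur regulator, rose 1.55-fold. All 14 iron-sulfur cluster assembly genes passed, 8 higher and 6 lower, with iscS-I 2.34-fold and the chaperone gene hscA 2.0-fold higher and the cluster carrier gene erpA 7.99-fold lower. Of 24 pyoverdine and iron uptake genes 10 rose and 9 fell: the synthesis genes pvdA and pvdH rose 1.43-fold and 1.84-fold, the receptor gene fpvA rose 1.52-fold, and pvdL and pvdY fell 3.76-fold and 3.91-fold. The pyoverdine sigma factor gene pvdS did not pass (1.13-fold, adjusted p 0.67).

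Other lists also held genes in both directions. In heat shock and protein quality control 12 rose and 11 fell of 27, with ibpA 2.84-fold higher and dnaK 1.79-fold and hslU 2.49-fold lower. Of 28 TCA cycle genes 12 rose and 14 fell, of 45 respiratory genes 18 rose and 14 fell (the dehydrogenase gene ndh 3.84-fold lower), and of 39 metal resistance genes 17 rose and 9 fell, with copS 4.51-fold and the zinc transport gene znuC 2.64-fold higher. Of 17 RND multidrug efflux genes 6 rose and 10 fell, of 23 genes for fatty acid and membrane lipid synthesis 13 rose and 7 fell, of 54 genes for outer membrane porins and cell wall 31 rose and 12 fell (adjusted p 0.097, adjusted p 0.11 with an estimated correlation and adjusted p 0.037 after quantile normalisation), and of 28 exopolysaccharide and adhesion genes 11 rose and 5 fell. Of 19 general stress and stationary phase genes 9 rose and 7 fell, with rpoS 1.74-fold higher and the stringent starvation gene sspA 9.98-fold lower. All 3 genes for the metabolism of polyhydroxyalkanoate, a storage polymer, fell by 2.04 to 2.44-fold (phaA, phaB and phaC-II), and 3 of 4 type VI secretion genes rose (clpV 1.69-fold). In nitrogen assimilation 11 rose and 13 fell of 28, and in prophage, pyocin and mobile elements 1 rose and 1 fell of 7. Of 43 flagellar and chemotaxis genes 21 fell and 16 rose, among the latter the export gene fliP 3.02-fold; the set test gave adjusted p 0.38, and without replicate 2 of the 6 h controls adjusted p 0.014, and adjusted p 0.061 with an estimated correlation. Median and mean differed in sign in iron-sulfur assembly (0.29 and -0.05), fatty acid synthesis (0.25 and -0.08), general stress (0.06 and -0.28), pyoverdine (0.09 and -0.07) and prophage genes (-0.01 and 0.03). Adjusted over the list alone, 11 rose and 14 fell in nitrogen assimilation, and the counts of the lists above were otherwise unchanged. With 69.4% of all genes past the threshold, every tested list passed fry except pyoverdine (adjusted p 0.33), heat shock (0.27), fatty acids (0.087) and general stress (0.33). Lists that camera did not pass were among these calls: oxidative stress (fry 0.00019) and flagella (1.8e-06) as lower and outer membrane genes (2.9e-10) as higher.

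Dissolved iron changed 3971 of 5720 genes, 2020 higher and 1951 lower, and of the 719 with an absolute log2 difference of at least 1, 528 were lower. These libraries also had fewer reads than the 24 h controls, and the 5 most abundant genes took 9.88 to 10.48% of their reads against 5.73 to 6.46%.

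**Figure D2:**
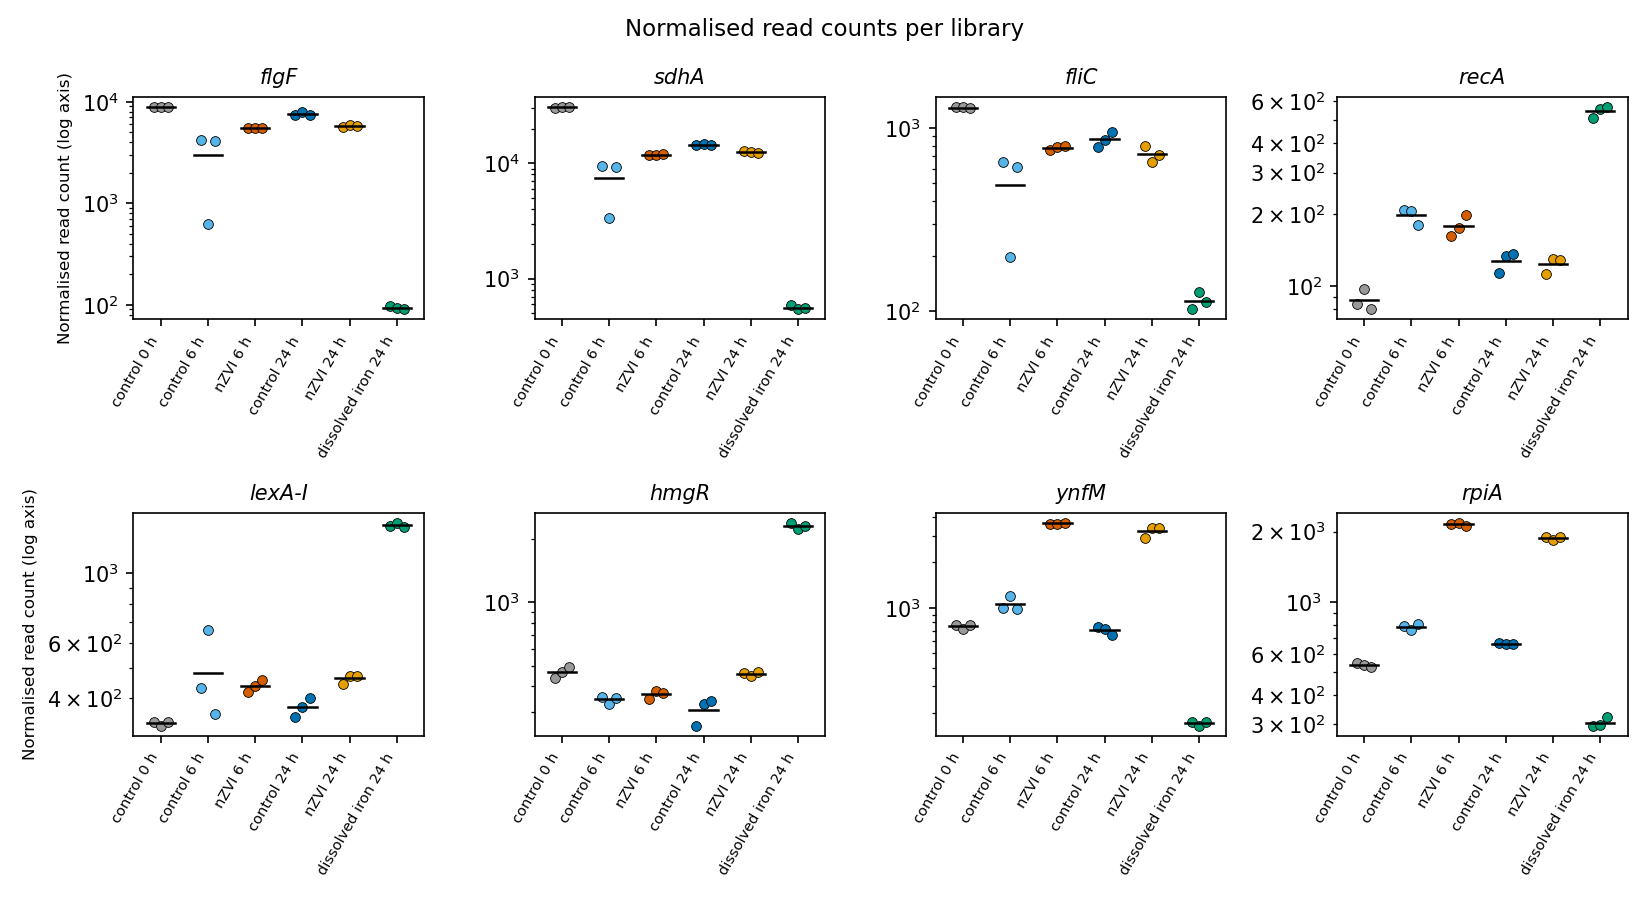
Normalised read counts (log axis) of 8 genes in each library, with points for the 3 flasks of each group and bars for group means. flgF, sdhA and fliC are lowest in dissolved iron, recA, lexA-I and hmgR are highest there, and ynfM and rpiA are higher with nZVI than in the controls of the same hour.

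**Figure D3:**
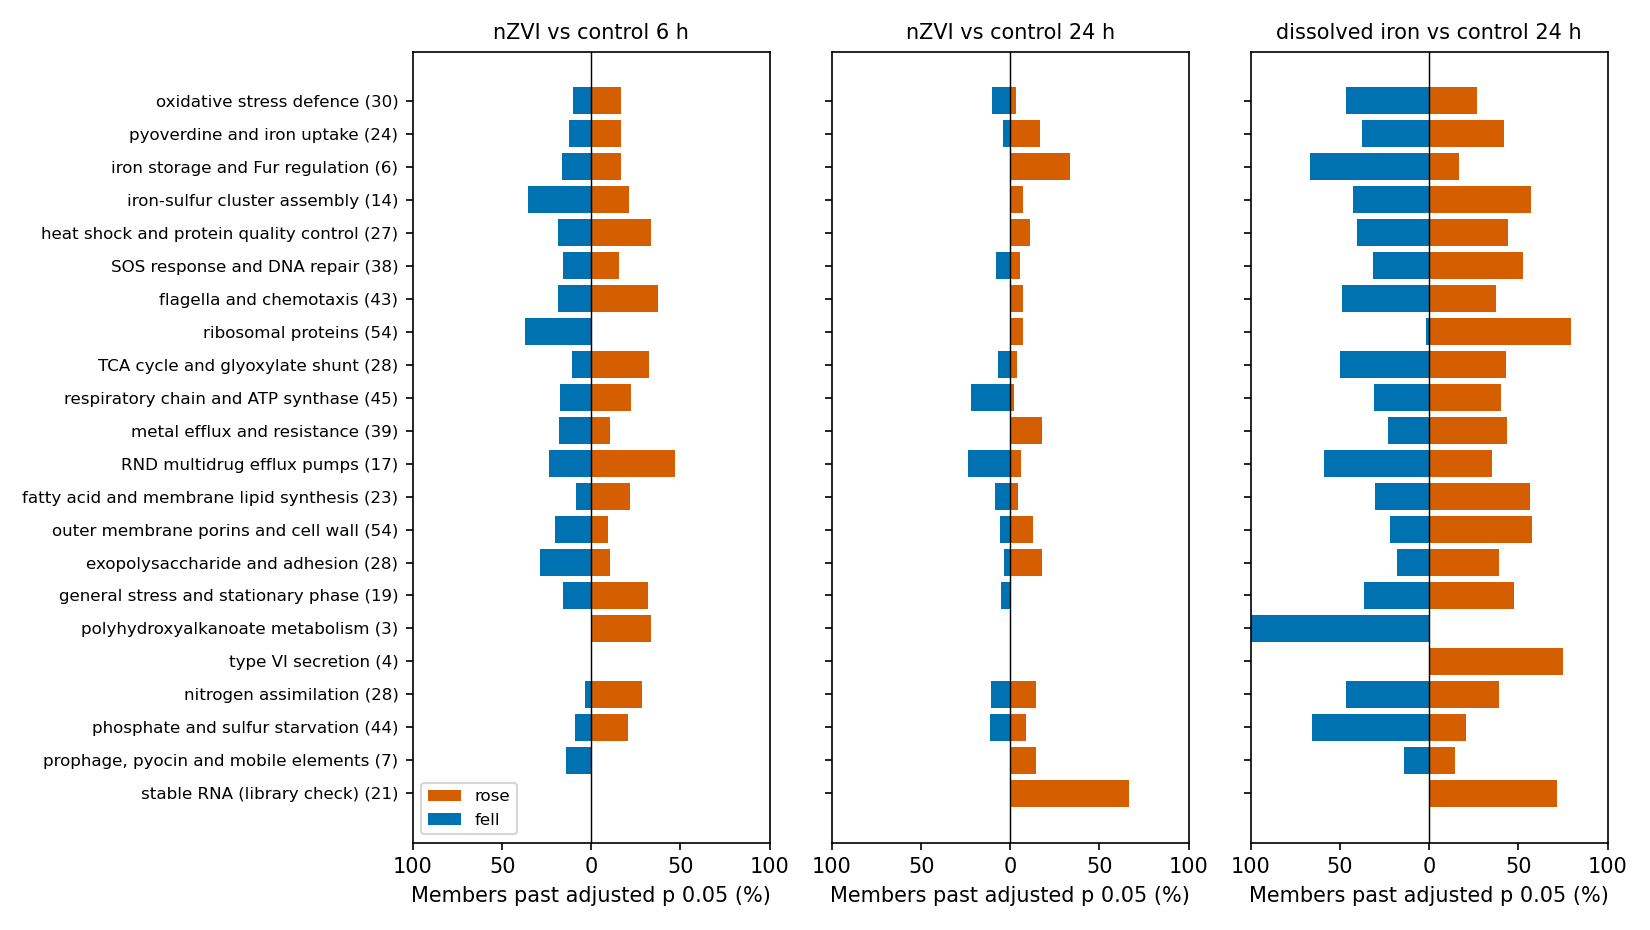
Percent of each gene list that rose (right, orange) or fell (left, blue) past adjusted p 0.05 for the 3 exposures, with list sizes in brackets. Of 54 ribosomal protein genes 20 were lower after 6 h of nZVI and 43 higher with dissolved iron than in the controls of the same hour.

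The direct comparison of both exposures at 24 h asks which changes with particles differ from those with iron in solution. Among the largest differences, flgF had 5755.6 ± 155.1 normalised counts with nZVI against 93.8 ± 3.83 with dissolved iron, 61.3-fold higher (log2 difference 5.08, SE 0.41, adjusted p 6.05e-09), and sdhA was 22.3-fold higher with nZVI. flgG, flgH and flgI were 57.7, 58.0 and 26.7-fold higher. hmgR, argH, sulA, pcaD and pcaB were 5.06, 3.45, 3.73, 4.36 and 3.54-fold lower with nZVI. ynfM and rpiA, looked up here after their values were seen, went the other way with dissolved iron: ynfM had 170.8 ± 5.21 normalised counts there and rpiA 304.9 ± 14.4, below the 24 h controls by log2 differences of -1.66 (SE 0.07, adjusted p 2.72e-12) and -0.95 (SE 0.05, adjusted p 1.86e-11). Ribosomal protein genes were lower with nZVI (39 of 54 lower, 1 higher, adjusted p 1.7e-06, and adjusted p 0.031 with an estimated correlation), and phosphate and sulfur genes were higher (28 of 44 higher, 9 lower, adjusted p 0.017, and adjusted p 0.093 with an estimated correlation). When adjusted over the list alone, 42 ribosomal protein genes were lower and 1 higher. Flagella and chemotaxis genes gave 21 higher and 10 lower (adjusted p 0.11), and without replicate 2 of the 6 h controls adjusted p 0.00072, and adjusted p 0.029 with an estimated correlation. Outer membrane and cell wall genes gave 11 higher and 27 lower (adjusted p 0.068), and adjusted p 0.045 without that library. In all 3629 genes passed, 1845 higher and 1784 lower with nZVI, or 1638 and 2124 with libraries rescaled to the same median.

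Some genes passed with both exposures at 24 h. Of the 830 genes changed by nZVI, 713 also passed with dissolved iron, 314 higher in both, 284 lower in both and 115 in opposite directions. pcaC and copS rose in both, and the oxidase gene cioB and the efflux gene mdtA fell in both, with dissolved iron the larger: pcaC 7.3-fold against 2.28-fold, copS 4.51-fold against 2.18-fold, cioB 2.96-fold lower against 1.37-fold lower and mdtA 2.38-fold lower against 1.31-fold lower. In 588 of the 713 the change was larger with dissolved iron. Both comparisons use the same 3 control flasks, which alone makes them alike. Across genes, which are not independent replicates, the differences correlated with r 0.541 (Spearman 0.566). In 100 simulations of unchanged groups that shared controls r was 0.463 to 0.536. There the shared controls were the only source of r, so setting the r values side by side cannot decide how much the exposures share. The covariance of the differences was 0.0826 against a simulated mean of 0.00467. With no change set, the simulations gave 0 genes past the threshold as higher in both, lower in both or in opposite directions. Independent lists would share 140.6 higher and 147.3 lower, an expectation that leaves out the shared controls. The shared count of 598 was 321 after quantile normalisation (213 higher, 108 lower), 1566 without replicate 2 of the 6 h controls (576 and 990) and 1430 with only the groups compared (491 and 939). Leaving out 1 of the shared 24 h controls could bring it below 321, with the range given under the processing.

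The change of the nZVI effect between 6 h and 24 h was tested as an interaction. Each hour of nZVI is set against its own controls, so a change of the controls between the hours enters too. tufB, the glyoxalase gene gloB and the cell shape gene mreB were lower with nZVI at 6 h and higher at 24 h: their log2 differences were -0.7 and 0.34, -0.53 and 0.75, and -0.6 and 0.53, and the interaction was 1.04 (SE 0.1, adjusted p 3.29e-06), 1.28 (SE 0.14, adjusted p 1.31e-05) and 1.13 (SE 0.17, adjusted p 0.000141). Of 54 ribosomal protein genes 25 shifted up and 2 down (adjusted p 4e-05, and adjusted p 0.07 with an estimated correlation), as did 14 up and 5 down of 28 exopolysaccharide and adhesion genes (adjusted p 0.029, and adjusted p 0.075 with an estimated correlation; without replicate 1 of the 6 h controls adjusted p was 0.052) and 14 of 21 stable RNA genes (adjusted p 0.00015, and adjusted p 0.51 with an estimated correlation). Of 28 TCA cycle genes 5 shifted up and 14 down (camera adjusted p 0.32). Without replicate 2 of the 6 h controls 6 shifted up and 15 down (camera adjusted p 0.017, and adjusted p 0.12 with an estimated correlation). In all 2325 genes passed, 1006 shifting up and 1319 down.

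The unexposed controls ask how cells in reservoir water changed over time without an exposure. No group was kept in growth medium, so the water, time and the move from culture cannot be told apart. From 0 h to 6 h lolC rose from 389.6 ± 34.7 to 4383.7 ± 545.6 normalised counts, 11.3-fold (log2 difference 3.23, SE 0.08, adjusted p 9.9e-16), recX rose 8.99-fold, the folate gene folD-II 8.52-fold, the serine dehydratase gene tdcG-III 6.48-fold and the ribosomal gene rpsC 10.1-fold. The succinate dehydrogenase genes sdhA, sdhB, sdhC and sdhD fell 4.16, 4.23, 4.73 and 4.8-fold, and flgK fell 3.2-fold, a log2 difference of -2.02 that was -1.21 without replicate 2 of the 6 h controls. Ribosomal protein genes rose in the controls too, 41 of 54 with 1 lower (adjusted p 1.1e-07, and adjusted p 0.016 with an estimated correlation). Beside them 12 of 21 stable RNA genes rose (adjusted p 0.051, and adjusted p 0.91 with an estimated correlation), and rRNA took 0.071 to 0.103% of reads against 0.024 to 0.029% at 0 h. Phosphate and sulfur genes fell, 28 of 44 with 6 higher (adjusted p 0.0038, and adjusted p 0.068 with an estimated correlation). In all 3655 genes passed, 1726 higher and 1929 lower at 6 h.

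By 24 h the controls lay nearer to 0 h. The hydroxybutyrate dehydrogenase gene bdhA fell from 1430.4 ± 120.9 to 215.9 ± 6.38 normalised counts, 6.62-fold (log2 difference -2.34, SE 0.07, adjusted p 1.28e-13), and cpsG, hsdM, ispE and sdhC fell 6.33, 4.45, 3.61 and 2.37-fold. The efflux genes emrA, emrB and mdtC rose 3.28, 3.11 and 2.73-fold, ydgK 3.43-fold and the cell wall gene pbpC 2.56-fold. Of 17 RND efflux genes 6 rose and none fell (adjusted p 0.00068, and adjusted p 0.2 with an estimated correlation; 10 rose without replicate 2 of the 6 h controls), and of 44 phosphate and sulfur genes 16 fell and 4 rose (adjusted p 0.024, and adjusted p 0.2 with an estimated correlation). Flagella and chemotaxis genes gave 4 higher and 5 lower of 43 (adjusted p 0.6), but 6 higher and 20 lower without replicate 2 of the 6 h controls (adjusted p 0.0011, and adjusted p 0.036 with an estimated correlation). In all 1723 genes passed, 852 higher and 871 lower at 24 h (1062 and 748 with libraries rescaled to the same median), and 2677 when only these groups entered the fit or 2862 with library quality weights.

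The authors' deposited tables list genes under their adjusted p of 0.05, with positive values where the control was higher. They hold 1578 genes for 6 h nZVI (870 higher in exposed cells, 708 lower), 945 for 24 h nZVI (441 higher, 504 lower) and 3838 for dissolved iron (1944 higher, 1894 lower). Of these, 1525, 793 and 3822 also passed here in the same direction. Both nZVI counts depended on single libraries and on the groups in the fit, as given under the processing. In the 24 h nZVI table the fold change column is headed 6 hours, but its values match the log2 ratios of the recovered 24 h normalised counts. The median absolute gap was 0.00081 and the largest 0.0569 on the log2 scale.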

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

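The tests of replicate 2 of the 6 h controls, apart from a first test of its depth, those of the low reads of ribosomal protein genes and that of a few genes taking more of the reads were chosen after the result was seen, and the others were written before. The values without that library come from an alternative added after seeing the data.

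The difference between nZVI and its controls changed from 6 h to 24 h in 2325 genes by a test of that change itself. On the first principal component nZVI libraries lay at -3.4 to -2.9 at 6 h and at -7.8 to -6.4 at 24 h. The controls lay at 4.6 to 22.5 and at -16.2 to -13. A change of the controls over time can bring about such a result, and its part was not separated. Genes that shifted up were gloB, with a log2 difference of 1.28 (SE 0.14, adjusted p 1.31e-05), tufB with 1.04 (SE 0.1, adjusted p 3.29e-06), mreB with 1.13 (SE 0.17, adjusted p 0.000141), yajD with 1.35 (SE 0.29, adjusted p 0.00245) and the regulator gene bvgA with 1.24 (SE 0.35, adjusted p 0.0111). Without replicate 2 of the 6 h controls these were 1.13, 1.05, 0.93, 0.93 and 0.74. Genes that shifted down were the aminotransferase gene tyrB with -1.53 (SE 0.37, adjusted p 0.00412), flgI with -1.56 (SE 0.53, adjusted p 0.0263), flgH with -1.59 (SE 0.56, adjusted p 0.0304), flgF with -1.65 (SE 0.59, adjusted p 0.0319) and flgG with -1.6 (SE 0.6, adjusted p 0.0391). Without that library they were -1.0, -0.79, -0.77, -0.79 and -0.73, with adjusted p between 7.36e-18 and 5.15e-13, since the spread narrowed as well. The calls of flgF and flgG were lost without any 1 of the libraries, replicates 1 to 3, of the 24 h controls, the 6 h nZVI group and the 24 h nZVI group (adjusted p 0.0502 to 0.0601 and 0.0594 to 0.0702). That of flgH was lost without replicate 1 or 2 of the 24 h controls, replicate 1 or 3 of the 24 h nZVI group or replicate 1, 2 or 3 of the 6 h nZVI group (adjusted p 0.0515 to 0.0565). Single samples were not tested by their gap to the others of a group, since groups had 3.

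For the change of the nZVI effect, 1 of 100 splits of the samples, the real one, gave as many genes as 2325, and the highest other gave 600. This share under 0.05 argues against a chance allotment of flasks but does not exclude it. The other splits mix exposed and control flasks, which widens their spread and lowers their counts. Differences in the handling of whole groups are not covered. For 6 h nZVI, 24 h nZVI, dissolved iron, nZVI with dissolved iron and the controls at 6 h and 24 h, 10 splits are too few for a share under 0.05. The real counts there were 1778, 830, 3971, 3629, 3655 and 1723, and the highest of the other splits gave 3 for nZVI with dissolved iron and 0 for the rest.

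Replicate 2 of the 6 h controls differed from both siblings, with flgF and sdhA far lower. Lower depth is argued against by a mean chi-square per gene of 35.2 against the nearer sibling, which allows for counting noise, while pairs within the other groups gave 1.11 to 6.11. The first test, written before its result, counted genes differing by over 1 log2 between the siblings with one of them thinned to that depth. It gave 32, between its bounds of 20 and 100, against 30 unthinned and 339 and 342 for replicate 2, and was replaced by the chi-square. Admixture of dissolved iron RNA is argued against because genes lower with iron asked for 71.4% and genes higher for -0.4%, a gap of 71.8, and an exchange with another group because its highest mean correlation with one was 0.53 against 0.96 within that group. A true difference between flasks or a sample from outside the series stay open, and no biological explanation was tested.

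Apart from the 0 h and 24 h controls, groups with fewer reads lay further along the first principal component. The 24 h controls had the most reads and lay at -16.2 to -13, further along than the 0 h controls at -24.4 to -24.2. This pattern replaced an earlier one, the larger count with dissolved iron than with nZVI, whose tests gave 3770 and 1401 genes at equal total reads, against 4116 and 2110 in the same voom fit at full depth, 3918 without the 50 most abundant genes and 3860 after quantile normalisation. Fewer reads alone, as a source of counting noise, are argued against, since 0 h controls thinned to the lowest number of reads moved by at most -0.12 along it. Thinning keeps the expected share of each gene, so a small move was likely from the start. Other traits that go with few reads are not covered. Whether a few genes taking more of the reads lie behind the pattern was not decided by those 3918 genes. Scaling by median ratios depends little on a few genes, and the count of calls does not address the first component. A growing even background of reads stays open as a part: of the 100 most abundant genes of the 24 h controls 7% rose with dissolved iron and 84 fell, between the bounds set beforehand, and genes picked as abundant in a group tend to be lower in another. Such a background lowers abundant genes by about the same share, while these had quartiles of -2.46 and -0.59 and ran from -5.47 to 2.76 in log2 difference, looked at afterwards. The 5 most abundant genes took 9.88 to 10.48% of reads with dissolved iron against 5.73 to 6.46%, where it would lower that share. An effect of the exposures and of time on transcription is the biological alternative in the design and was not separated from it.

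Ribosomal protein genes carried few reads in all groups. An even background of reads over all genes is argued against as the whole source over all libraries. Their median lay at -1.23 log2 reads per kilobase from that of other genes, which had an interquartile range of 1.69. In single groups it lay from -1.91 to -0.85. In the 6 h controls (-0.86) and with dissolved iron (-0.85) it did not reach the bound of the test, so a background stays open as a part there. Short length stays open: among other genes of 600 bases or less the median ribosomal protein gene lay at percentile 25.5, just above the bound of 25. Lengths came from another strain and were had for 53 of the 54 genes but for 15.3% of all genes. Household genes written down as abundant also lay low, at -0.64 log2 reads per kilobase from other genes, with lengths for 14 of 25. Low reads may thus not be particular to ribosomal protein genes. Reads lost in library preparation or counting were not tested, nor was any biological explanation. Counting of opposite-strand reads was not tested either, as the strand setting is not given, and it would bear on all genes.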

How the results depend on the processing

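The alternatives voom, log2 of the normalised count plus 1, library quality weights and the removal of replicate 2 of the 6 h controls beyond its own comparisons were chosen after the result was seen. No named gene or list that passed in either of the fits compared reversed, judged for lists by the camera direction. Camera directions of lists that did not pass turned, as for flagella and chemotaxis without replicate 2 of the 6 h controls at 6 h nZVI (adjusted p 0.78 and 0.094) and 24 h nZVI (adjusted p 0.27 and 0.26). After quantile normalisation 3464 of 3480 shared calls with dissolved iron, 2962 of 2972 for the controls at 6 h and 1680 of 1682 for the change of the nZVI effect kept their direction, and the others reversed; in the other alternatives every shared call of a comparison kept it. With only the groups compared in the fit 45 genes passed at 6 h nZVI, all 45 shared with the deposited table, 1899 at 24 h nZVI and 2677 for the controls at 24 h, and the count shared by both 24 h exposures was 1430. Without replicate 2 of the 6 h controls that 6 h fit gave 1469, so this library's spread lowered it. Quantile normalisation gave 479 at 24 h nZVI, 321 shared by both exposures and 427 shared with the deposited table, and the cause was not tested. Library quality weights gave 2248 at 24 h nZVI, 2862 for the controls at 24 h and 1681 shared by both exposures. An added minimum of 1 on the absolute log2 difference, which removes genes by construction, left 15 at 6 h nZVI, 18 at 24 h nZVI, 719 with dissolved iron, 537 for nZVI with dissolved iron, 160 for the change of the nZVI effect, and 389 and 71 for the controls at 6 h and 24 h. With 1 library left out, 975 to 2124 genes passed at 6 h nZVI, 344 to 2074 at 24 h nZVI, 3718 to 4215 with dissolved iron and 1386 to 2573 for the controls at 24 h. Without 1 of the 24 h controls or replicate 2 of the 6 h controls, the only removals run for it, the count shared by both exposures ranged from 240 to 1566. With 1 library left out, the count shared with the deposited table ranged from 928 to 1501 at 6 h and from 339 to 945 at 24 h nZVI. At 24 h nZVI the lowest was without replicate 1 of the 24 h controls and the highest without replicate 2 of the 6 h controls. With the replicate number as a block the counts were 1727, 758 and 3946 for the 3 exposures. Of the named gene results outside the removals of a library 4128 kept their side of the threshold, 51 passed newly and 145 no longer passed, and of the list results 538, 9 and 13. In the removals of a library these were 2367, 37 and 186 for named genes and 1022, 12 and 6 for lists. Rescaling moved the median gene by at most 0.054 and -0.063 on the log2 scale. The lowest depth of 1434437 reads limits genes with few reads, and changes of 1.5-fold were recovered in 64 to 66% of simulated genes and the smallest simulated changes in 12 to 16%. Changes were simulated only in genes with a mean of at least 10 normalised counts, so these rates leave out genes with fewer. No simulated library stood apart, so these rates need not hold for the data.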

Other observations

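The test of dissolved iron with the change of the controls and the choice of the tmRNA were made after the result was seen, and the test of nZVI at both hours was written before.

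The tmRNA, which frees stalled ribosomes, had 43.0 to 50.4 normalised counts in the 0 h controls, 326.6 to 397.6 in the 6 h controls and 190.0 to 203.7 after 6 h of nZVI. It had 118.9 to 203.7 in the 24 h controls, 211.0 to 585.3 after 24 h of nZVI and 806.0 to 1106.6 with dissolved iron.

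A response to nZVI shared by both hours was tested by correlating the log2 differences at 6 h and 24 h, which share no library, across genes, which are not independent replicates. A correlation above 0.2 was predicted, and Pearson's r was -0.506 (Spearman's rho -0.584). Of the genes past the threshold at both hours 362 went in opposite directions, against 129.7 for independent lists, while 33 rose and 17 fell at both. Without replicate 2 of the 6 h controls r was -0.338 (rho -0.472). Library traits also moved in opposite ways: with nZVI reads were 2628143 to 2835150 against 1589029 to 2287065 in the controls at 6 h, and 2691897 to 2896121 against 3570060 to 4204283 at 24 h. The controls lay at 4.6 to 22.5 on the first principal component at 6 h and at -16.2 to -13 at 24 h. nZVI libraries moved less, from -3.4 to -2.9 at 6 h to -7.8 to -6.4 at 24 h, so changing controls may give such a correlation, which was not tested. ynfM and rpiA were among the genes that rose at both hours.

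The difference with dissolved iron at 24 h was set against the change of the controls from 0 h to 6 h, with no library in common. Across genes r was 0.757 (rho 0.759), and 0.678 (rho 0.72) without replicate 2 of the 6 h controls. Of the genes past the threshold in both 1303 rose and 1464 fell in both, against 609.5 and 658 for independent lists, and 212 went in opposite directions. sdhA and flgK fell and recX rose in both. Library traits also moved the same way in both. rRNA took 0.071 to 0.103% of reads in the 6 h controls against 0.024 to 0.029% at 0 h, and 0.087 to 0.132% with dissolved iron against 0.027 to 0.034% in its controls. Reads fell from 3334619 to 3828773 per library to 1589029 to 2287065, and from 3570060 to 4204283 to 1434437 to 1941247. Their part in the correlation was not tested. The relation was found in these data, and no independent data tested it.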
